A study of Homo sapiens with 4 samples.

How the data were processed

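Total RNA of OE33 cells was measured on 4 Affymetrix Human PrimeView arrays, 2 of cells given siRNAs against ARID1A and 2 of cells given non-targeting siRNAs. Per the labels' protocols, the cells were grown in medium with 15% serum, plated in 6-well plates, transfected with Lipofectamine after 24 hours at a final siRNA concentration of 50 nM, and harvested 48 hours after transfection, and 1 µg of RNA was labelled with biotin. Groups and replicate numbers were taken from the sample labels, and the series describes the replicates as biological. The labels do not say that arrays with the same number share a culture, a day or a batch, so the groups were compared without pairing.

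The deposited values are log2 expression per probe set, 1 column per array. Per the submitters' processing notes, RMA and Partek were used, with no version and no role given. RMA corrects the background, sets the arrays to a common distribution and summarises the probes of a probe set, so that a change in total mRNA per cell cannot be seen in these values and a change of a dim probe set is understated. The log2 scale was taken from the naming of RMA and from the range of the values, and was not set against scanner output, which was not used here. The scan dates and batches of the arrays are not given in the sources used here. No filter on probe sets is stated.

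The table held 49372 probe sets. The 79 Affymetrix control probe sets were left out of the tests, and 49293 were tested. Gene names came from the annotation of the platform, with symbols checked through the Entrez identifier against a RefSeq gene table of assembly GRCh38.p14. No symbol needed updating and 27 probe sets had an identifier absent from that table. Of the tested probe sets 44988 were paired with 1 gene, 1832 with several and 2473 with none, and only the first kind was named. Each of 18132 genes was represented by the probe set with the highest mean over the 4 arrays among those paired with it alone, a choice blind to the groups. Other probe sets of opposite sign are given for the genes named in the text. Of the 159 genes that the rule for named genes selects, 126 had other probe sets, and 32 of these had at least 1 of opposite sign, none past the test. No genomic positions are given, since the build behind the probe sets was not stated. Array probe sets ending in _s_at or _x_at hold probes that can match transcripts of other genes or similar sequences.

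Knockdown was compared with mock by limma (lmFit and eBayes, version 3.58.1, in R 4.3.3), two-sided, over all 4 arrays, and p-values were adjusted by Benjamini-Hochberg over the 49293 probe sets, with a threshold of 0.05. All adjusted p-values of single genes are from this fit, unless another is named. The fit had 2 residual degrees of freedom and a prior worth 3.62. Standard errors and 95% confidence intervals are those of the moderated fit, and SDs are over the 2 arrays of a group.

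For gene lists, camera was run with a preset correlation of 0.01 between genes, and again with the correlation estimated within each list, and fry was run on the same representative probe sets, each adjusted by Benjamini-Hochberg over 34 lists. With 2 residual degrees of freedom the estimated correlations are imprecise, and the test that uses them rests on those 2 degrees of freedom alone. The lists, the main tests, the rule for named genes and the first group of alternative settings below were fixed before the data were examined. The lists were drawn from textbook knowledge of chromatin, cell cycle, stress, metabolism, signalling, differentiation and the markers of other cell types, and some genes stand in more than 1 list. Members with no probe set of their own were not analysed here. Named genes were ARID1A and any SWI/SNF subunit past the test, the 15 genes with the largest rise and the 15 with the largest fall among those past it, and up to 4 members of each list with the smallest unadjusted p. ATF4, ARID1B, MYC and SLC7A11 were named beside these after their values were seen. Not all list members that the rule selects are named in the text, and one gene among the largest changes is not reported here.

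The procedure was tested on simulated data for the comparison of ARID1A knockdown with mock, with 49293 probe sets, of which 50 were changed at each of 4 sizes. Levels were those of the arrays, and each spread was drawn from the prior fitted by limma, whatever the level. Such data meet the assumptions of the fit, so the shares that follow need not hold for the real arrays. At a log2 change of 0.5 it recovered 0 of 50, at 1 it recovered 37 of 50 (74%), at 1.5 it recovered 49 (98%) and at 2 it recovered 50 (100%), and 4 of its 140 calls (2.86%) were false. In a second simulation of the same comparison the 19 cholesterol genes were shifted by 0.2. By camera that list was called (adjusted p = 3.02e-12) and 0 of 33 others, and with an estimated correlation the shifted list was missed (adjusted p = 0.506). Genes were drawn independently in it, so members of a list did not correlate. It cannot show how often camera with the preset calls lists whose genes do.

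The alternative settings of the first group were median centring of the arrays, quantile normalization, only probe sets above the median level, eBayes with an intensity trend and robust settings, a linear model without moderation, the mean of all probe sets of a gene, the replicate number as a block, and leaving out each array in turn, where the lone array of a group is assumed to vary like the other group. Those added after seeing the data were the crossed replicate block, a threshold of 0.1, the estimated correlation as a setting for the calls of lists, only probe sets without the _s_at or _x_at ending, and the SWI/SNF list without ARID1A. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.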

Results

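ARID1A encodes a DNA-binding subunit of the SWI/SNF (BAF) chromatin remodelling complex and is often mutated in human carcinomas. The series set out to find genes that lie downstream of ARID1A and might bear on the behaviour of tumour cells that lose it. OE33, an established human cell line from an adenocarcinoma of the oesophagus, was transfected with a pool of siRNAs against ARID1A or with a pool of non-targeting siRNAs, the latter called mock here. Each condition was measured in 2 biological replicates, so 4 Affymetrix Human PrimeView arrays were compared. An array gives no read depth, and the number of arrays limits the precision of every value below. Array medians were 5.92 and 5.90 on the log2 scale in the knockdown arrays and 5.89 and 5.93 in the mock arrays. Over all probe sets, the SD of the difference between the 2 arrays of a condition was 0.166 for knockdown and 0.160 for mock, and between arrays of different conditions it ran from 0.198 to 0.243. The 3′ probe set of the beta-actin control exceeded its 5′ probe set by 1.21 and 1.10 log2 units in the knockdown arrays and by 1.04 and 0.995 in the mock arrays, a measure of RNA integrity that moved with the condition and so stands beside every gene group described here. The same measure for GAPDH was 0.201 and 0.215 in the knockdown arrays and 0.199 and 0.211 in the mock arrays.

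The first comparison asked whether the transfection lowered ARID1A itself. ARID1A mRNA fell 3.43-fold, from a log2 level of 9.31 ± 0.037 (SD, n = 2) in mock to 7.53 ± 0.0025 (SD, n = 2) in knockdown cells, at its brightest probe set, 11719858_a_at. The log2 change was -1.78 with a 95% confidence interval of -1.96 to -1.60, which left 29.2% of the mock level (25.8% to 33.0%). The adjusted p from limma was 0.0218. Of the 6 probe sets paired with ARID1A alone, 4 passed the test, and the other 3 of these had log2 changes of -1.37, -1.39 and -1.61. The probe set 11742019_a_at had a change of -0.36 (adjusted p = 0.213). The remaining one, 11746832_a_at, had a change of 0.11 (adjusted p = 0.678) and a mock level of 3.28, at the 8.28th percentile of all probe sets. No other SWI/SNF subunit passed the test among the 30 measured, of which 1 was higher and 5, with ARID1A, were lower at an unadjusted p under 0.05. Adjusted over the list alone 2 were lower, ARID1A and SS18 (0.0257). The paralogue ARID1B had a log2 change of 0.25 (adjusted p = 0.439), SS18 of -0.43 (0.0984), PBRM1 of -0.37 (0.141) and SMARCC1 of -0.29 (0.175).

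**Figure D1:**
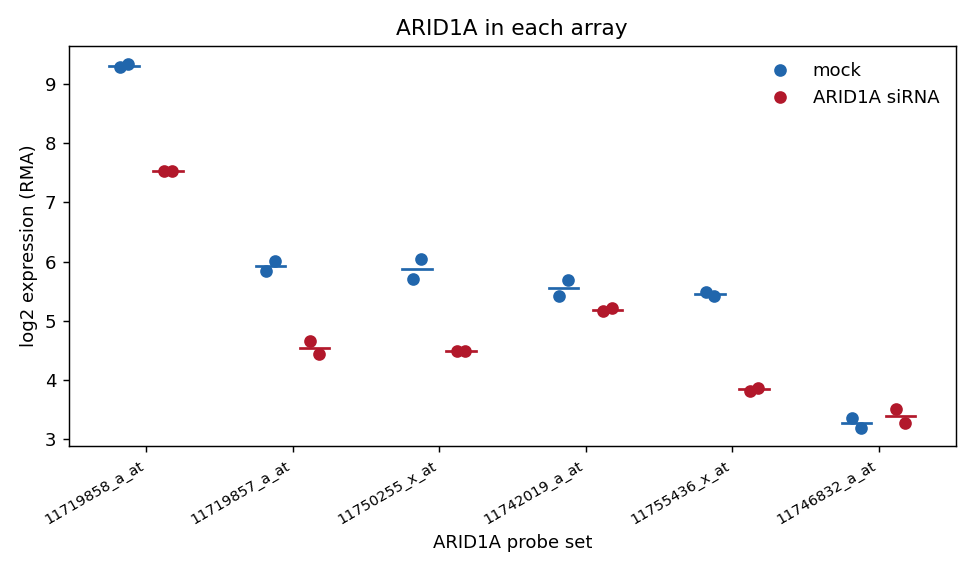
Log2 expression (vertical axis) of the 6 ARID1A probe sets (horizontal axis) in each of the 2 mock and 2 ARID1A siRNA arrays (points), with a bar at each mean. At the brightest probe set the mock arrays averaged 9.31 and the knockdown arrays 7.53.

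The second comparison asked which other genes differed between ARID1A knockdown and mock cells. HPGD, which encodes the prostaglandin-degrading enzyme hydroxyprostaglandin dehydrogenase, had the largest rise, and RAB38, a small GTPase of vesicle traffic, had the largest fall after ARID1A. HPGD was 3.15-fold higher (log2 change 1.65, SE 0.139, adjusted p = 0.0319), at 8.66 ± 0.158 in knockdown against 7.001 ± 0.238 in mock cells (SD, n = 2 each). RAB38 was 3.09-fold lower (log2 change -1.63, SE 0.101, adjusted p = 0.0218), at 7.90 ± 0.111 against 9.53 ± 0.130. In all, 73 of 18132 genes passed the test, 34 higher and 39 lower, and 23 of them changed at least 2-fold, 9 higher and 14 lower. Counted by probe set, 156 of 49293 passed, 74 higher and 82 lower. At an unadjusted p under 0.05 in limma, 1770 of the 18132 genes were higher and 1315 lower. The counts of list members at that p, above and below, are to be read beside these. With each array centred on its median, 671 probe sets passed, 403 higher and 268 lower.

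After HPGD, the largest rises included those of FGFBP1 and ARID5B. FGFBP1, a secreted carrier of fibroblast growth factors, had a log2 change of 1.32, and ARID5B, another DNA-binding protein with an ARID domain, one of 1.22. DDIT4, an inhibitor of mTORC1 signalling induced by stress, rose 2.12-fold, and CYP3A5, a drug-metabolising cytochrome P450, rose 2.09-fold. HOPX, an atypical homeodomain protein, PLAAT4, a phospholipid-modifying enzyme, and ACSM3, a medium-chain acyl-CoA synthetase, rose 2.03-fold, 2.02-fold and 2.01-fold, each with an adjusted p of 0.0499. ELF5, an ETS-family transcription factor of epithelia, had a log2 change of 0.98, the desmosomal cadherin DSC2 of 0.96 and TNFRSF19, a receptor of the TNF receptor superfamily, of 0.89. MTMR11, PRR15L and ENPP5 were also among the 15 largest rises, with changes of 0.96, 0.92 and 0.86.

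After ARID1A and RAB38, the largest falls were those of LHFPL6, MT2A and SDHD. AXL, a receptor tyrosine kinase, was 2.32-fold lower (log2 change -1.21), and ARHGDIA was 2.43-fold lower (-1.28). PHLDB2, which anchors microtubules near adhesion sites, had a change of -0.94. SDHD, a membrane anchor of succinate dehydrogenase, fell 2.56-fold, and TOMM6, a part of the mitochondrial protein import pore, fell 2.07-fold. MT2A, a metal-binding metallothionein, fell 2.80-fold from one of the brighter signals on the array, a log2 level of 13.2 in mock cells. LHFPL6 fell 2.94-fold, the ciliary transport gene WDR35 2.53-fold, SLC2A4RG 2.24-fold and the carbonic anhydrase gene CA13 2.16-fold. The nucleolar exonuclease gene ISG20L2 had a log2 change of -1.14. TMEM158 and TMEM214 each fell 2.06-fold.

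Over the 30 genes with the 15 largest rises and the 15 largest falls, other probe sets were present for 25. All of them passed for 7 genes, and none passed for 11, whose values follow. All 7 others of HPGD, all 4 of SDHD, all 3 of ARHGDIA and both of RAB38 passed. By contrast, the second probe set of WDR35 had a change of -0.02 (adjusted p = 0.943), that of LHFPL6 of -0.32, that of MT2A of -0.40 and that of AXL of -0.48, none past the test. The called probe set of WDR35 ends in _s_at and its second does not. The fall of WDR35 therefore has no backing from a gene-specific probe set. All probe sets of SDHD, ARHGDIA, MT2A, ISG20L2 and HOPX end in _s_at or _x_at, as do the only ones of TOMM6 and TMEM158. The changes of these genes have no such backing either. Among the others of SDHD, 2 had identical values (change -1.27, SE 0.0887). Another probe set of HPGD had the same change and SE as the probe set used (1.65 and 0.139). The passes of SDHD and HPGD are therefore not all separate measurements. The 2 others of CA13 had changes of -0.05 and -0.42, those of TMEM214 of -0.29 and -0.39, those of SLC2A4RG of -0.42 and -0.57 and those of ARID5B of 0.48 and 0.55, each smaller than at the probe set used. The others of TNFRSF19 had changes of 0.89 and 0.22, those of ENPP5 of 1.02 and 1.21 and those of HOPX of 1.34 and 1.24, and none of these passed either. One probe set of PLAAT4 had a change of -0.02 and one of PHLDB2 of 0.28, opposite in sign to the call and also not past it. The calls sit close to the threshold, since the smallest adjusted p in limma was 0.0218. With any one of the 4 arrays left out, too few degrees of freedom were left for even ARID1A to pass, though its log2 change stayed at -1.80 to -1.75. That setting therefore does not tell how stable the calls of other genes are. Of the 73 genes, 30 were called on probe sets whose probes can also match other sequences. Without such probe sets 12 genes passed, 4 higher and 8 lower, all 12 among the 73. Genes called on unshared probe sets also lost the call there, as the fit and the adjustment were redone. The drop therefore does not measure the part of shared probes.

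**Figure D2:**
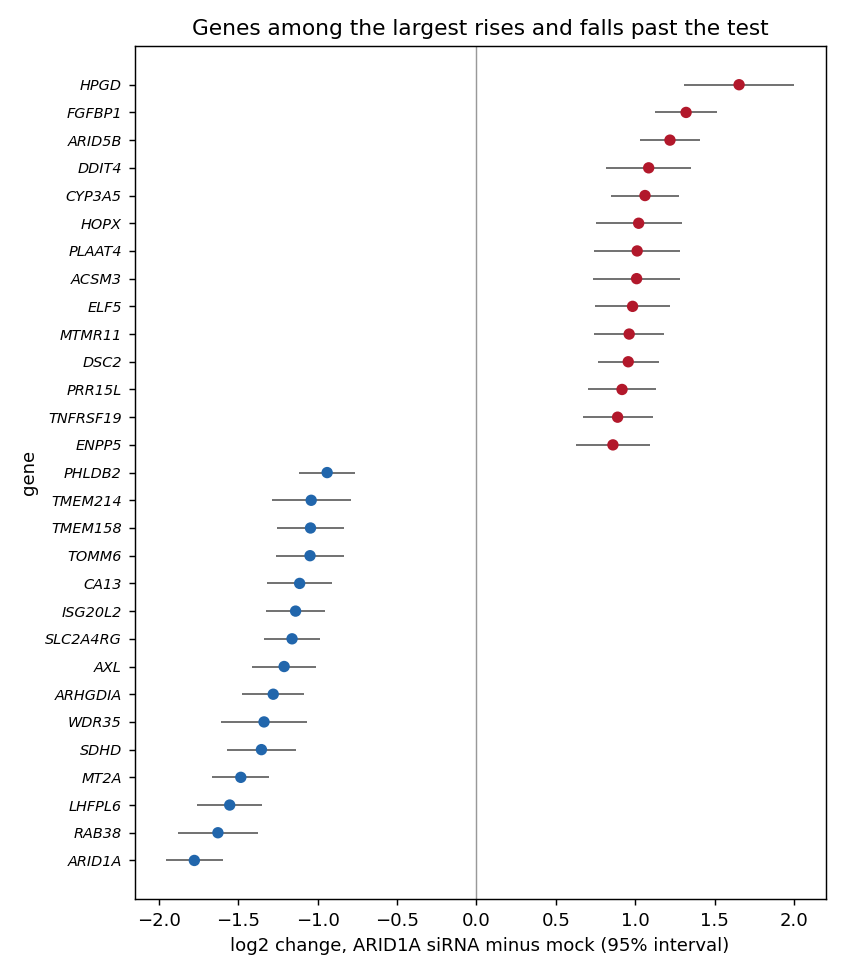
Log2 change, ARID1A siRNA minus mock (horizontal axis), of genes among the 15 largest rises and the 15 largest falls past the test (vertical axis), 29 in all, with 95% confidence intervals as bars. The changes run from -1.78 for ARID1A to 1.65 for HPGD.

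The third comparison asked whether genes of a shared function moved together, over 34 lists. By limma's camera, 11 lists differed from the other genes, 10 higher and 1 lower, and 7 lists did so without knockdown replicate 1. None of the 11 calls held with a correlation between genes estimated within each list. There the camera adjusted p was 0.787 for the interferon list, 0.606 for the apoptosis list and 0.457 for each of the other 9. That setting tests on the 2 residual degrees of freedom, so a lost call does not by itself show correlated members. The estimates lay below the preset 0.01 for the NRF2 (0.0011), squamous (-0.030), PI3K (-0.031) and fatty acid (-0.049) lists. For the other called lists they ran from 0.035 (antigen presentation) to 0.214 (interferon). Most members that carried these shifts did not pass the test singly.

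The genes of ribosome biogenesis and MYC targets were lower in the knockdown cells. Of 29 measured, 28 had a negative log2 change, MYC itself had a change of 0.00, and the median was -0.17 (camera adjusted p = 2.49e-08, and 0.457 with an estimated correlation). ODC1, the rate-limiting enzyme of polyamine synthesis, fell 1.58-fold (adjusted p = 0.0499) and was the 1 member past the test, both over all probe sets and adjusted over the list alone. Not past it were SRM, spermidine synthase, at -0.34, the nucleolar protein NOLC1 at -0.29 and the pre-ribosomal RNA processing factor RRP9 at -0.27. The genes of the ribosomal proteins, a separate list, had a median of 0.02 over 30 measured (adjusted p = 0.269).

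The genes of cholesterol synthesis and uptake were higher. All 19 measured had a positive change, with a median of 0.24 (camera adjusted p = 6.21e-07, and 0.457 with an estimated correlation). In limma 0 passed over all probe sets, 9 had an unadjusted p under 0.05, and 7 passed when adjusted over the list alone. INSIG1, which retains the sterol sensor in the endoplasmic reticulum, had a change of 0.51, ACAT2 of 0.41, the sterol transporter STARD4 of 0.38 and the sterol desaturase SC5D of 0.38. Without knockdown replicate 2 the median was 0.149 (adjusted p = 9.97e-05). Fatty acid synthesis had a median of 0.09 over 17 measured (adjusted p = 0.0479, and 0.457 with an estimated correlation). None of its members passed over all probe sets, with 5 higher and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 3 were higher and 1 lower. Acetyl-CoA synthetase ACSS2 had a change of 0.59, the desaturases SCD and FADS1 of 0.38 and 0.28, and GPAM, the first enzyme of glycerolipid synthesis, of -0.49. The fatty acid median was 0.122 without knockdown replicate 1, 0.0906 without mock replicate 1 and 0.0897 with the arrays centred on their medians, none below the main value. The call was still lost in all of these settings (camera adjusted p = 0.0597 for the last). It was also lost under quantile normalization (0.0810), with the filter on dim probe sets (0.0725), with either replicate block (0.0562 and 0.0612) and with unshared probe sets (0.101). Without knockdown replicate 2 the fatty acid median was 0.138 (0.0485).

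The targets of ATF4, the transcription factor of the amino-acid stress response, were higher. Of 27 measured, 21 had a positive change, with a median of 0.25 (camera adjusted p = 5.83e-05, and 0.457 with an estimated correlation). DDIT4 was the 1 member past the test over all probe sets. Adjusted over the list alone, 13 were higher and 2 lower. PHGDH, the first enzyme of serine synthesis, had a change of 0.87 (adjusted p = 0.0501), asparagine synthetase ASNS of 0.83 (0.0561) and the cystathionine lyase CTH of 0.64 (0.0984). ATF4 mRNA itself had a change of 0.31 (adjusted p = 0.153). SLC7A11, also a member of this list, had a negative change, which is given below with the NRF2 list. The chaperones of the endoplasmic reticulum, a separate list, had a median of -0.05 over 21 measured (adjusted p = 0.672).

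The list of NRF2 targets and glutathione genes was also higher, with 17 of 22 positive and a median of 0.14 (camera adjusted p = 7.29e-04, and 0.457 with an estimated correlation). The glutathione peroxidase GPX2 rose 1.78-fold (adjusted p = 0.0444) and the aldo-keto reductase AKR1C3 rose 1.63-fold (0.0482), while its other probe set, close to the background, had a change of -0.20 (0.515). Adjusted over the list alone, 6 were higher and 1 lower. AKR1B10 had a change of 0.48 and the efflux pump ABCC3 of 0.43, while SLC7A11, the cystine transporter, had a change of -0.28. The hypoxia and glycolysis list had 21 of 27 positive and a median of 0.13 (adjusted p = 7.29e-04, and 0.457 with an estimated correlation). None of its members passed over all probe sets, 10 were higher and 1 lower at an unadjusted p under 0.05, and 4 were higher adjusted over the list alone. The aldolase gene ALDOC had a change of 0.54, the angiogenic factor VEGFA of 0.51, PFKFB4 of 0.46 and the histone demethylase KDM3A of 0.32. Without mock replicate 1 the hypoxia median was 0.0847 (0.00318).

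Interferon response genes were higher as a list, with 28 of 37 positive and a median of 0.11 (camera adjusted p = 0.00585, and 0.787 with an estimated correlation). None passed over all probe sets, 10 were higher and 1 lower at an unadjusted p under 0.05, and adjusted over the list alone 7 were higher and 1 lower. OAS1 had a change of 0.68, the RNA sensor IFIH1 of 0.64, IFIT2 of 0.52 and IFIT3 of 0.49. Antigen presentation genes had 16 of 18 positive and a median of 0.11 (adjusted p = 0.0102, and 0.457 with an estimated correlation). None passed over all probe sets, 6 were higher and 1 lower at an unadjusted p under 0.05, and 3 were higher adjusted over the list alone, among them the immunoproteasome subunit PSMB9 at 0.43, CD74 at 0.42 and the peptide transporter TAP1 at 0.41. Without knockdown replicate 2 the adjusted p was 0.0587 for both lists, and without mock replicate 2 it was 0.0554 for the interferon list. The interferon median was 0.0612 without knockdown replicate 2 and 0.0639 without mock replicate 2, and the antigen presentation median was 0.0713 without mock replicate 1 and 0.172 without mock replicate 2.

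Squamous differentiation genes had 19 of 29 positive and a median of 0.06 (camera adjusted p = 0.0298, and 0.457 with an estimated correlation). DSC2 rose, and adjusted over the list alone 4 were higher. SPRR3, a cornified envelope protein, had a change of 0.68, the basal keratin KRT15 of 0.61 and the protease inhibitor CSTB of 0.31. Apoptosis regulators had 19 of 30 positive and a median of 0.08 (adjusted p = 0.0298, and 0.606 with an estimated correlation). None passed over all probe sets, with 8 higher at an unadjusted p under 0.05, and 1 passed adjusted over the list alone, the inflammatory caspase CASP1 at 0.67. The PI3K and receptor kinase list had 18 of 30 positive and a median of 0.05 (adjusted p = 0.0368, and 0.457 with an estimated correlation). None passed over all probe sets, with 7 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone. ERBB3 had a change of 0.60 (adjusted p = 0.0525), FGFR3 of 0.58, EGFR of 0.40 and IRS2 of 0.39, and on the 2 probe sets of ERBB3 with no probes shared with other sequences the changes were -0.23 and 0.29, neither past the test. Without knockdown replicate 1 the adjusted p of all 3 lists was 0.0814, without mock replicate 1 it was 0.148 for the squamous and 0.0874 for the PI3K list, and without mock replicate 2 it was 0.141 for the apoptosis list. The squamous median was 0.116 without knockdown replicate 2 and 0.0974 without mock replicate 2, and the apoptosis median was 0.124 without mock replicate 1 and 0.0484 without mock replicate 2. The PI3K median was 0.0332 without knockdown replicate 1, 0.0347 without mock replicate 1 and 0.0846 without mock replicate 2, and with unshared probe sets it was -0.00042 (adjusted p = 0.384). The PI3K call was also lost under quantile normalization (0.0972), with the filter on dim probe sets (0.0758), with the mean of probe sets (0.116) and with the crossed block (0.0627). With the filter the squamous median was 0.256, and the squamous call was lost with unshared probe sets (0.0567). The apoptosis call was lost under quantile normalization (median 0.0426, adjusted p = 0.0810), with the filter (0.0971, 0.123) and with unshared probe sets (0.0360, 0.101).

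**Figure D3:**
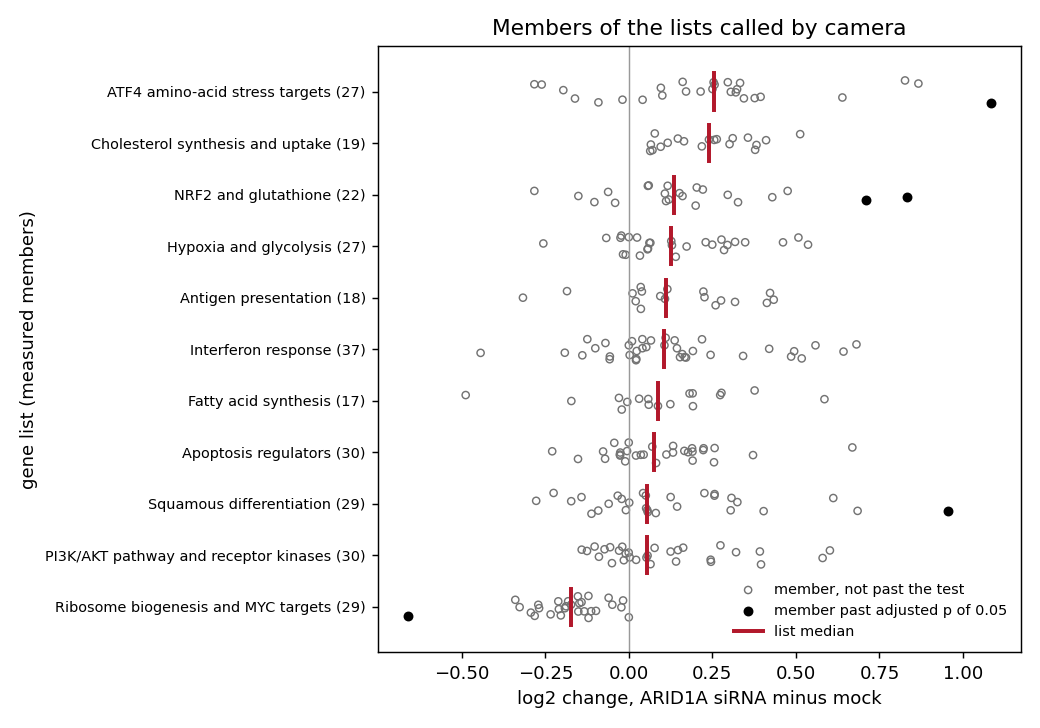
Log2 change, ARID1A siRNA minus mock (horizontal axis), of each measured member (points) of the 11 lists called by camera (vertical axis), with filled points for members past an adjusted p of 0.05 and a bar at each list's median. The medians run from -0.17 for ribosome biogenesis and MYC targets to 0.25 for ATF4 targets.

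The other 23 lists did not differ from the remaining genes by camera. Mitosis genes had a median of -0.02 over 31 measured (adjusted p = 0.231). None passed over all probe sets, with 1 higher and 5 lower at an unadjusted p under 0.05, and adjusted over the list alone 4 were lower: the spindle factor TPX2 at -0.57, MYBL2 at -0.43, HMMR at -0.34 and the kinase PLK1 at -0.30. The mitosis list passed without knockdown replicate 2 (adjusted p = 0.0361) and without mock replicate 2 (0.0455). DNA replication genes had a median of -0.03 (adjusted p = 0.693), with MCM3 at -0.31. The list of CDK inhibitors and G1 cyclins had a median of -0.03 (0.918), with CDKN1C at 0.54 and CDK6 at -0.28. Genes of p53 signalling had a median of 0.07 (0.114), with PHLDA3 at 0.41 and MDM2 at -0.36, and they passed without mock replicate 1 (adjusted p = 0.04999). DNA repair genes had a median of 0.02 (0.772). In these 4 lists no member passed the test in limma, with 1, 2, 7 and 3 members higher and 3, 1, 2 and 2 lower at an unadjusted p under 0.05. Over all 18132 genes, 1770 were higher and 1315 lower at that p. Adjusted over the list alone, CDKN1C was higher and no other member of these 4 lists passed.

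In the list of NF-kB targets and inflammatory cytokines, CXCL1, a neutrophil chemokine, rose 1.66-fold (adjusted p = 0.0444), CXCL8 had a change of 0.54 and TNFAIP2 of -0.48, with a list median of 0.03 (camera adjusted p = 0.251). Among YAP and TEAD targets, AXL fell, the ectonucleotidase NT5E had a change of 0.63 and FJX1 of -0.34, with a median of -0.0024 (0.505). Among Wnt targets, TNFRSF19 rose, AXIN2 had a change of 0.69 and LEF1 of -0.45, with a median of -0.03 (0.772). The oxidative phosphorylation list had SDHD as the 1 member past the test and a median of 0.03 over 27 measured (0.772). The SWI/SNF list had a median of 0.02 (0.772). Immediate early genes had a median of 0.01 (0.898), with 6 higher and 4 lower at an unadjusted p under 0.05, among them the AP-1 subunit FOSL1 at -0.59, KLF4 at 0.50 and KLF2 at -0.50. TGF-beta targets had a median of 0.01 (0.277), with 5 higher at an unadjusted p under 0.05, among them the pseudoreceptor BAMBI at 0.51 and BMP4 at 0.37. Adjusted over the list alone, 2 were higher and 1 lower for NF-kB, 1 and 3 for YAP, 4 and 1 for Wnt, 0 and 1 for oxidative phosphorylation, 5 and 3 for immediate early genes and 2 and 0 for TGF-beta.

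Epithelial markers had a median of 0.04 (camera adjusted p = 0.251), with the membrane protease PRSS8 at 0.51, and mesenchymal and invasion markers a median of -0.00070 (0.918), with the urokinase PLAU at 0.45, MMP14 at 0.36 and SNAI2 at -0.45. Columnar and intestinal markers had a median of -0.05 over 36 measured (0.772), with CEACAM5 at 0.84 (adjusted p = 0.0517), CEACAM6 at 0.53, HNF4G at 0.52 and ANXA10 at -0.67. No member of these 3 lists passed the test in limma, with 5 higher in each and 0, 3 and 3 lower at an unadjusted p under 0.05, and adjusted over the list alone with 1, 2 and 4 higher and 0, 0 and 2 lower. Histone genes had a median of -0.04 (0.469), with H2BC12 at -0.56, Polycomb and chromatin regulators one of -0.02 (0.469), with SUZ12 at -0.33, and genes of the siRNA machinery one of -0.06 (0.569), with DGCR8 at -0.35. Markers of cell types that a pure cell line should lack had medians of -0.04 for fibroblasts (0.469), -0.04 for leukocytes (0.469) and -0.09 for endothelium (0.0906), and the endothelial list passed without mock replicate 1 (0.0476). No member of these 6 lists, nor of the immediate early, TGF-beta, ribosomal protein or chaperone lists, passed the test, and at an unadjusted p under 0.05 the histone list had 1 higher and 4 lower, the Polycomb list 2 and 3, the siRNA list 1 and 3, the fibroblast list 0 and 2, the leukocyte list 0 and 1, the endothelial list 0 and 3, the ribosomal protein list 1 and 0 and the chaperone list 3 and 2. Adjusted over the list alone, 1 was higher among the chaperones and 1 lower in each of the histone, fibroblast and endothelial lists, and 0 passed in the Polycomb, siRNA, leukocyte and ribosomal protein lists.

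Some list members named above had another probe set of opposite sign, none of them past the test. These lay at 0.19 and 0.29 for MDM2, -0.14 for PFKFB4, -0.09 for AXIN2, -0.04 for CEACAM6, 0.17 for H2BC12, -0.04 for FGFR3, -0.05 for HNF4G and -0.02 for MMP14. They also lay at -0.09 and -0.11 for EGFR, -0.01 and -0.06 for CASP1, 0.01 for SS18, 0.12 for SLC7A11 and 0.05 for 2 of PBRM1, and 4 of the 8 others of LEF1 ran from 0.04 to 0.13. Other probe sets of the same sign are not all given, and some lay close to 0. Among them were those at -0.05 for KLF2, 0.02 for ABCC3 and 0.04 for CEACAM6.

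The median, the mean and the direction given by camera differed in sign for 6 of these lists. The means were -0.06 for SWI/SNF, 0.02 for CDK inhibitors, 0.07 for Wnt targets, 0.01 for mesenchymal markers, 0.0030 for columnar markers and -0.03 for oxidative phosphorylation. By fry, which asks whether the genes of a list move one way on balance and does not set them against other genes, the adjusted p was 0.0423 for the NF-kB, NRF2, hypoxia, PI3K, squamous, ribosome biogenesis and histone lists, and also for the SWI/SNF list, which holds the silenced gene. Without ARID1A, a choice made after the data were seen, the SWI/SNF list had an adjusted p of 0.523 and the 7 others one of 0.0483. In both runs it was above 0.05 for the remaining 26. Lists called by camera were among these. With ARID1A kept, their fry adjusted p was 0.0553 for cholesterol, 0.0559 for ATF4 and 0.0674 for antigen presentation. It was 0.0892 for both fatty acid synthesis and apoptosis, and 0.197 for interferon.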

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

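These measures were looked at outside the gene comparisons, and each was higher in both knockdown arrays than in both mock arrays. With 10 control measures and 2 arrays per group, chance alone would put both knockdown arrays on top for 16.7% of the measures, and 4 of the 10 did so, with none the other way round. The difference between the 3′ and 5′ probe sets of beta-actin was 0.132 log2 units larger in the knockdown arrays, a signal of RNA integrity in probes that the comparisons do not use. The spiked poly-A control lys, a bacterial transcript added to each RNA sample before labelling, was 0.259 higher in the knockdown arrays. The spiked poly-A control phe was 0.247 higher, while the dap and thr controls of the same set differed by 0.011 and 0.022. The hybridization control bioC was 0.110 higher, while bioB, bioD and cre differed by 0.048, 0.035 and -0.0091.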

How the results depend on the processing

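The crossed block, the threshold of 0.1, the estimated correlation, the restriction to unshared probe sets and the SWI/SNF list without ARID1A were chosen after seeing the data. ARID1A stayed lower under each alternative, at -1.81 to -1.75 at its main probe set and -1.07 over the mean of its probe sets, but lost the threshold without moderation (-1.78, adjusted p = 0.223) and without any one array (-1.80 to -1.75, adjusted p 0.244 to 0.521), where fewer degrees of freedom are left. Against 156 probe sets and 73 genes, median centring gave 671 (403 higher, 268 lower) and 286 (178 and 108), quantile normalization 297 and 138 (69 and 69), the filter on dim probe sets 2106 and 977 (608 and 369), trend and robust settings 3249 and 1573 (965 and 608), the threshold of 0.1 gave 895 and 406, and unshared probe sets 23 and 12. The mean of the probe sets of a gene gave 356 genes (64 of them shared with the 73) and no probe set count. Without moderation 2 probe sets and 0 genes passed, and no camera result was given. At an unadjusted p under 0.05 there were 6029 and 2591, against 7969 and 3085 in the main fit. Leaving out 1 array gave 0 to 0 probe sets and genes in limma, with 4531 to 6814 probe sets and 1722 to 2523 genes at an unadjusted p under 0.05, and 7 to 10 lists, 7 of them without knockdown replicate 1. The estimated correlation gave 0 lists, unshared probe sets 7, and the SWI/SNF list without ARID1A 11. The cause of these differences was not tested, apart from settings that change what is tested or the threshold. These are the filter, the unshared probe sets, the omitted arrays and the threshold of 0.1. The model without moderation lacks the degrees of freedom that the prior adds. All 73 genes were kept under median centring, quantile normalization and the trend, and 71 under the filter. Sign changes were seen for ARID1A at 11746832_a_at without knockdown replicate 1 (-0.0035, with a range of -0.0035 to 0.228 over the omitted arrays), and with unshared probe sets, where another probe set stands for the gene, for ERBB3 (-0.23), MBD3 (0.15), PBRM1 (0.0474) and RPL3 (-0.27), none of them past the test in either setting. The median of the PI3K list was also below 0 there, at -0.00042 against 0.0545. Other medians of called lists that moved by over 1.5 times, omitted arrays apart, were as follows. With the filter the squamous median was 0.256 and the fatty acid median 0.153, against 0.0552 and 0.0872. With unshared probe sets the interferon median was 0.0523 against 0.107, that of antigen presentation 0.187 against 0.112 and that of apoptosis 0.0360 against 0.0759. With the mean of probe sets the medians were 0.0683 for interferon, 0.0451 for apoptosis, 0.0223 for PI3K and 0.0771 for hypoxia, the last against 0.127, and with quantile normalization that of apoptosis was 0.0426. The ATF4, cholesterol, NRF2, hypoxia and ribosome biogenesis lists kept their camera call in all settings that gave one but the estimated correlation. The ribosomal protein list passed with the trend (0.0230) and the p53 list with the mean of probe sets (0.0305). The fatty acid, apoptosis and PI3K lists lost theirs under quantile normalization (adjusted p 0.0810, 0.0810 and 0.0972), the filter (0.0725, 0.123 and 0.0758) and unshared probe sets (0.101, 0.101 and 0.384), the last also with the mean of probe sets (0.116), and the squamous list with unshared probe sets (0.0567). Dim probe sets limit what can be seen, since at low signal RMA values understate changes.

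The labels give no pairing, and deviations of same-numbered arrays from their group means correlated at -0.202. A block leaves fewer degrees of freedom for the test, as an omitted array does. Calls of single genes lost with either block therefore do not tell whether pairing matters. With the replicate block 0 probe sets and 0 genes passed in limma, with 5535 and 2154 at an unadjusted p under 0.05, ARID1A stayed at -1.78 (adjusted p = 0.217), and 10 lists passed, the fatty acid list being lost (0.0562). The crossed replicate block, chosen after this correlation was seen, gave 0 probe sets and 0 genes, with 9467 and 3635 at an unadjusted p under 0.05, 9 lists, with the fatty acid (0.0612) and PI3K (0.0627) lists lost, and ARID1A at -1.78 (adjusted p = 0.187).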

Other observations

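The genes in this paragraph passed the test but lie outside the rule for named genes and were chosen after their values were seen. Among signalling genes, the kinases MAPKAPK3, MAP2K4 and CHUK, the last a kinase of the NF-kB pathway, fell by 0.76, 0.72 and 0.72 on the log2 scale. The ubiquitin ligase genes RNF11 and TRAF7 fell by 0.78 and 0.63. The serine/threonine kinase PIM1 rose by 0.67, the interleukin-1 co-receptor IL1RAP by 0.64, and NRG1, a growth factor that binds ERBB3, by 0.82. Among regulators of epithelial transcription, TFAP2A rose by 0.77 and GRHL3 by 0.68, and the ectodysplasin receptor EDAR rose by 0.75. The histone acetyltransferase gene KAT6A fell by 0.67, the translation initiation factor gene EIF2S2 by 0.81 and the cytochrome oxidase subunit gene COX6A1 by 0.87. Other probe sets of opposite sign lay at 0.08, 0.18 and 0.20 for MAP2K4, at -0.14, -0.07 and -0.09 for NRG1, at -0.13 for EDAR, -0.06 for TFAP2A and -0.01 for IL1RAP, none of them past the test. How stable these calls are to leaving out an array cannot be told, since too few degrees of freedom were then left for even ARID1A to pass.

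The 3 patterns below were picked after the gene and list results were known, and the tests on single probe sets, shared probe sets and the siRNA pool were chosen only after the results they measure were seen. The ribosome biogenesis list was lower in the knockdown arrays by camera, a call lost with an estimated correlation (adjusted p = 0.457). A shift that depends on signal level would place its median within random lists of the same size matched on mean level, but at -0.173 it lay below all 10000 of them, whose central 95% ran from -0.0403 to 0.0794. A chance choice of members would leave other genes of the same function near 0, but 28 such genes outside the list had a median of -0.100, at the 0.06th percentile of their own matched lists, and 22 of the 28 were lower. These tests take genes as independent and do not weigh variation that the genes of a list share between cultures, nor a difference in growth or RNA quality between the cultures, and with 2 arrays per condition these stay open beside an effect of ARID1A loss, which may lower this group as a hypothesis.

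The cholesterol and amino-acid stress lists were higher in the knockdown arrays by camera, and both calls were lost with an estimated correlation (adjusted p = 0.457 for each). Neither list passed by fry (adjusted p = 0.0553 and 0.0559). Their medians of 0.240 and 0.254 lay at the 100th percentile of matched random lists, whose central 95% ended at 0.104 and 0.0777, which argues against a shift with signal level but, since genes are taken as independent, not against variation that they share between cultures. Raised ATF4 activity would also raise the tRNA synthetase genes that ATF4 is known to activate, none of them in the list: these 10 had a mean log2 change of 0.209 (SD 0.183, 8 positive) and 7 other synthetases one of -0.081 (SD 0.141, 1 positive), a difference of 0.290 (exact permutation p = 0.00447, two-sided, over genes, which are not independent replicates). A raised ATF4 response would give such a difference, as a hypothesis, though 6 of the 27 list members had a negative change, SLC7A11 among them. The difference does not tell an effect of ARID1A loss from one of culture density or nutrient supply. What the cholesterol genes follow was not tested. Of the other lists called by camera, the PI3K (0.0545) and fatty acid (0.0872) medians lay within the central 95% of their own matched lists, at percentiles 89.2 and 95.2. The medians of the remaining called lists lay outside it.

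Among the genes called beside ARID1A, an artefact of single probe sets would leave their other probe sets on either side of 0 alike. The mean of a gene's other probe sets above the median level lay on the called side for 45 of 46 genes (97.8%, exact binomial 95% interval 88.5% to 99.9%). For genes called on probe sets shared with other sequences, the mean of their gene-specific ones above that level did so in 17 of 17 (100%, interval 80.5% to 100%). Over probe sets of all levels these means did so for 51 of 54 genes (94.4%, interval 84.6% to 98.8%) and 21 of 21. Taken singly, 19 of 130 probe sets lay on the other side, in 14 genes, among them AKR1C3 and PLAAT4, and so did 3 of the 41 gene-specific ones, in FBXW11 (0.03), PHLDB2 and TFAP2A, all 3 below the median level. Only 54 of the 72 genes had another probe set, and only 21 of the 30 called on shared ones had a gene-specific one. The others, SDHD, ARHGDIA and MT2A among the latter, could not be tested. For the tested genes as a set, not for each gene, these shares argue against either explanation. WDR35 counts as on the called side at -0.02 against -1.34, and probe sets of one gene can share probes. The median ratio of these means to the called change was 0.81 and 0.91 above the median level, and 0.54 and 0.62 over all levels, so the size of a call stays open. Silencing of other transcripts by the siRNA pool predicts more falls than rises: of 22 genes changed at least 2-fold besides ARID1A, 13 fell (59.1%, interval 36.4% to 79.3%, exact binomial p = 0.524, two-sided). This decides nothing, and effects of ARID1A loss and of the pool on other transcripts cannot be told apart here, since 1 pool was used and no siRNA sequences were analysed here.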
